A study of Saccharomyces cerevisiae with 13 samples.

How the data were processed

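The measurements were probe set signals of 13 Affymetrix yeast arrays, hybridised with biotin-labelled total RNA from 5 control, 5 spermidine-treated and 3 spermine-treated samples. The deposited values are linear signal intensities made by the authors with MAS5, per the labels. Its version is not given in the sources used here. The 2% trimmed mean was 500 after rounding on each array, so 1 scaling factor per array had been applied before deposit. Present calls were not used here. Groups and replicate numbers came from sample titles.

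Of 9335 probe sets, 60 controls were left out, 6504 name 1 gene, 328 several and 2443 none in the platform annotation used, and all 6504 gene identifiers matched the reference gene table. Signals were taken to log2 without a pseudocount. A rule set before the data were examined asked for quantile normalization if array medians differed by more than 1.25-fold. They differed by 1.29-fold, so quantile normalized values are the main ones and the values as deposited became the alternative, the reverse of the roles first written. The dimmest 25% of probe sets by mean over all arrays were left out (signal under 37.8), and the brightest probe set stood for its gene, which left 5102 genes, with 281 several-gene and 1012 unnamed probe sets tested apart. Of 250 genes with several tested probe sets, 0 had probe sets changing in opposite directions between spermidine and control at an unadjusted p under 0.01. The other contrasts were not checked in this way. A group counted as at background when it lay under the 95th percentile of 19 non-yeast control probe sets, and folds against it are given as at least that against the background level.

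Group means were fitted over all 13 arrays in limma 3.58.1 (R 4.3.3) with an intensity trend, and the 3 contrasts were spermidine minus control, spermine minus control and spermine minus spermidine. Adjusted p-values are Benjamini-Hochberg, with a threshold of 0.05, and ± after a log2 value is the standard error. Signals with SD are the deposited values. The 47 gene lists were fixed before the data were examined, and 39 genes are in more than 1 list. They were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, with adjustment over all lists and contrasts. Named genes are the 12 largest rises and falls per contrast with control, 8 for the direct contrast, among called genes without overlap between the groups and above the median level in a group, up to 4 called members per list, and polyamine genes. HAC1, HIS3, HIS5, GCV1, GCV2 and MTD1 with spermine, members moving against their list, and small RNA genes, were named after their values were seen.

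On data simulated with known changes, the spermidine contrast recovered 18.2% of genes changed by a log2 of 0.5, 83.6% at 1 and 98.5% at 2 over 5102 genes, and the spermine contrast 11.9%, 80.6% and 96.9% over 5099 genes. The simulated arrays vary independently, unlike the real ones. Alternatives were the other normalizations, pseudocounts of 16 and 64, other filters, no trend, array weights, 2-group fits, replicate blocks, probe set means, each array left out, and splits of the controls. Fits with only some control and spermine arrays, with these arrays as a block, and without small RNA genes were added after the data were seen. Results that were not called and changed sign while not called were counted as the same. A comparison of stress genes between the arrays that deviate together and the others was also run and set aside, because those arrays had been set apart by the same expression values. Its direction had been written down the wrong way round, and no result here rests on it. A first form of the small RNA test, which compared those controls with the others, was replaced for the same reason by the range over all controls. The ACT1 ratio test first asked only whether the 3 arrays lay within the range of the others, which could not argue against degradation, and was replaced. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15.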

Results

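Transcript levels were measured on 13 one-colour Affymetrix arrays, hybridised with total RNA from cultures of the budding yeast Saccharomyces cerevisiae. The series asks which genes respond when spermidine or spermine is given to a mutant that its title calls polyamine-deficient. Polyamines are small positively charged molecules made from ornithine. There were 5 control arrays, 5 arrays of spermidine-treated cells and 3 arrays of spermine-treated cells. Doses and treatment times are not given in the sources used here. The median signal ranged from 125 to 162 between arrays. Signals of replicate arrays correlated between 0.932 and 0.982 for controls, 0.939 and 0.984 for spermidine and 0.954 and 0.977 for spermine, across genes, which are not independent replicates. The labels do not say that the arrays came from separate cultures, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision of each value.

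The genes deleted in the mutant, SPE3 for spermidine synthase and FMS1 for a polyamine oxidase, were examined first. The signal of SPE3 lay between 0.570 and 13.8 on all 13 arrays, and that of FMS1 between 1.10 and 8.10. Both stood between the 1.02 and 10.5 percentiles of their arrays, and below the 95th percentile of the non-yeast control probe sets averaged over a group, 16.3 in controls, 17.9 with spermidine and 18.1 with spermine. The mean SPE3 signal was 5.35 ± 1.55 (SD, n = 5) in controls, 5.80 ± 5.37 (SD, n = 5) with spermidine and 2.84 ± 2.22 (SD, n = 3) with spermine. Control labels name no genotype, and the control arrays had the same low signals.

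Spermidine against control addressed the response to the polyamine that the deleted synthase makes. Genes of sulfate assimilation, lysine, biotin and NAD synthesis were among the largest rises, and genes of stress defence and respiration were among the falls. MET2, homoserine acetyltransferase, had a signal of 28.4 ± 18.2 (SD, n = 5) in controls and 1217 ± 1267 (SD, n = 5) with spermidine (log2 5.31 ± 0.50, SE, limma adjusted p = 2.62e-06). BIO5, a transporter of a biotin precursor, rose 29.8-fold (log2 4.90 ± 0.21, adjusted p = 8.66e-10), and LYS9, saccharopine dehydrogenase, 14.2-fold (log2 3.83 ± 0.15, adjusted p = 7.15e-10). BNA2, the first enzyme of NAD synthesis from tryptophan, was at background in the mean of the controls and at least 46.4-fold higher with spermidine. Against controls 2 and 3 alone it was 17.7-fold higher. MPC3, a mitochondrial pyruvate carrier subunit, fell from 7670 ± 2385 (SD, n = 5) to 669.6 ± 218 (SD, n = 5), and the catalase gene CTT1 from 1724 ± 1535 (SD, n = 5) to 144 ± 65.8 (SD, n = 5). The control mean of CTT1 is carried by controls 2 and 3, at 3722 and 3048, the other controls lying between 521 and 678.

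In the list of methionine synthesis and sulfate assimilation, 20 of 26 measured genes rose and 1 fell, and the counts adjusted over the list alone were the same 20 and 1 (median log2 2.17, camera adjusted p = 1.39e-09, adjusted p = 0.372 with an estimated correlation). STR3, cystathionine beta-lyase, rose 38.1-fold (log2 5.25 ± 0.31), MET14, adenylylsulfate kinase, 21.9-fold (log2 4.45 ± 0.33), and MET3, ATP sulfurylase, 13.5-fold (log2 3.76 ± 0.36). The member that fell was MET31, a zinc finger regulator, by 0.72 on the log2 scale. The sulfate permease gene SUL1 was at background in controls and at least 16.5-fold higher. Of the S-adenosylmethionine cycle, 8 of 18 genes rose and 2 fell, or 10 and 2 adjusted over the list alone (median log2 0.44, camera adjusted p = 0.0160, adjusted p = 0.468 with an estimated correlation). MHT1, MMP1 and SAM3 rose by log2 3.44, 3.22 and 2.13, the latter pair being transporters of S-methylmethionine and S-adenosylmethionine, while ARO9 and SPE2 fell by 2.35 and 0.82. The call of this list ends against controls 1, 4 and 5 (median 0.27, adjusted p = 0.0609), and its median is 0.59 against controls 2 and 3. Methionine, arginine, lysine, NAD and biotin synthesis are recalled as themes that the study itself names, so their lists are not independent evidence of direction.

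All measured genes of biotin synthesis and uptake rose, 6 of 6, also 6 adjusted over the list alone (median log2 3.16, camera adjusted p = 7.26e-07, adjusted p = 0.158 with an estimated correlation), in a list that is not independent evidence. BIO3 rose 14.4-fold, BIO4 13.4-fold and BIO2, biotin synthase, 5.94-fold. In lysine synthesis 8 of 9 genes rose, 8 adjusted over the list alone (median log2 2.14, camera adjusted p = 6.00e-09, adjusted p = 0.0542 with an estimated correlation), with LYS1 up 11.3-fold and LYS2 4.77-fold. Arginine synthesis had 6 of 8 genes higher, 6 adjusted over the list alone (median log2 1.52, camera adjusted p = 8.23e-05, adjusted p = 0.158 with an estimated correlation), led by ARG4 at 5.22-fold and ARG1 at 4.28-fold. For NAD synthesis 8 of 14 genes rose and 2 fell, 8 and 2 adjusted over the list alone (median log2 0.99, camera adjusted p = 0.00475, adjusted p = 0.291 with an estimated correlation), and BNA3, BNA1 and BNA4 were 4.64, 3.88 and 3.39-fold higher. PNC1, nicotinamidase, and NMA1 fell by 1.24 and 0.61 on the log2 scale. These 3 lists are likewise not independent evidence. YJR079W, which lies beside BNA2 in the reference table, rose with it by log2 4.92 ± 0.41.

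The unfolded protein response list, genes induced when proteins misfold in the endoplasmic reticulum, rose with 19 of 21 members higher and 1 lower, 19 and 1 adjusted over the list alone (median log2 1.17, camera adjusted p = 2.54e-12, adjusted p = 0.0237 with an estimated correlation). EUG1, a protein disulfide isomerase, rose 8.94-fold, DER1, a factor of endoplasmic reticulum protein degradation, 8.15-fold, INO1, inositol phosphate synthase, 7.69-fold and SIL1, a nucleotide exchange factor of the chaperone Kar2, 6.63-fold. The member that fell was HAC1, the transcription factor of this response, by 0.90 on the log2 scale. In the phosphate regulon 8 of 12 genes rose and 1 fell, 9 and 1 adjusted over the list alone (median log2 0.81, camera adjusted p = 6.78e-04, adjusted p = 0.263 with an estimated correlation). The phosphate transporter gene PHO84 rose 14.0-fold and VTC3 of polyphosphate synthesis 3.37-fold, and PHM8 fell by log2 1.33. In branched-chain amino acid synthesis 8 of 13 genes rose, 8 adjusted over the list alone (median log2 0.56, camera adjusted p = 0.00591, adjusted p = 0.458 with an estimated correlation), among them LEU4 at 2.65-fold and LEU1 at 2.06-fold.

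Of the general stress genes, 17 of 46 fell and 1 rose, 22 and 2 adjusted over the list alone (median log2 -1.07, camera adjusted p = 4.00e-05, adjusted p = 0.827 with an estimated correlation). TKL2, ALD3 and RTC3 fell by 3.30, 3.01 and 2.93 on the log2 scale, and the vacuolar mannosidase gene AMS1 rose by 3.28. Among heat shock chaperones 8 of 24 fell, 9 adjusted over the list alone (median log2 -0.71, camera adjusted p = 0.00179, adjusted p = 0.685 with an estimated correlation), HSP104 by 1.96. The controls themselves differed in these genes: the mean of the general stress list lay 1.03 and 0.99 log2 units above the control mean on controls 2 and 3, and at -0.77, -0.49 and -0.76 on controls 1, 4 and 5, while the spermidine arrays lay between -1.45 and -0.70. Against controls 1, 4 and 5 the medians with spermidine were -0.30 for general stress (adjusted p = 0.0374) and -0.21 for heat shock (adjusted p = 0.102), and against controls 2 and 3 they were -1.89 and -1.66. Values of single genes called with spermidine also differed between controls 1, 4 and 5 and controls 2 and 3. The log2 values were -2.23 and -4.69 for CTT1, -1.76 and -5.60 for TKL2, -1.63 and -5.09 for ALD3, -2.29 and -3.88 for RTC3, -1.36 and -2.86 for HSP104, -2.43 and -5.19 for TMA10 and -2.60 and -4.73 for PUT4. Further pairs were -3.29 and -4.38 for PNS1, -3.18 and -3.98 for MPC3, -2.48 and -3.76 for CYC7 and -0.95 and -1.63 for MTD1, and among the rises 5.89 and 4.44 for MET2, 5.47 and 4.10 for YJR079W, 2.84 and 3.80 for MMP1, 1.09 and 1.87 for LEU4, 3.60 and 2.81 for AMS1, 0.97 and 2.06 for ATX1, 3.32 and 2.37 for INO1, 5.49 and 4.90 for STR3 and 4.08 and 3.49 for BIO3. The MET2 signals on controls 1, 4 and 5 were 12.9 to 20.8, around the background level of 16.3, so the size of its 5.89 is uncertain.

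Of the nuclear-encoded respiratory chain and ATP synthase genes, 18 of 35 fell, and 20 fell and 1 rose adjusted over the list alone (median log2 -0.43, camera adjusted p = 5.84e-05, adjusted p = 0.566 with an estimated correlation). CYC7, a cytochrome c isoform, fell 7.98-fold (log2 -3.00 ± 0.39) and NDE1, an external NADH dehydrogenase, 2.08-fold. In ribosome biogenesis 14 of 86 genes fell, 6 adjusted over the list alone (median log2 -0.24, camera adjusted p = 0.00273, adjusted p = 0.860 with an estimated correlation). The 14 are a share near that of all genes, of which 751 of 5102 fell. BMS1 had log2 -1.09 and RPA135, a subunit of RNA polymerase I, -0.89. The median of the list was -0.40 against controls 1, 4 and 5 and 0.01 (camera adjusted p = 0.990) against controls 2 and 3. Hexose transporters had 6 of 9 genes lower and 1 higher, 7 and 1 adjusted over the list alone (median log2 -1.02, camera adjusted p = 0.0114, adjusted p = 0.433 with an estimated correlation), HXT6 by log2 -1.25 and HXT7 by -1.04, and the glucose sensor gene RGT2 rose by 0.76. In the iron regulon 11 of 26 genes fell and 3 rose, 11 and 3 adjusted over the list alone (median log2 -0.32, camera adjusted p = 0.0493, adjusted p = 0.768 with an estimated correlation). The cell wall mannoprotein genes FIT2 and FIT3 fell by 2.34 and 1.48, while ATX1, a copper chaperone, FTH1 and FTR1 rose by 1.41, 0.74 and 0.53. Against controls 1, 4 and 5 the hexose and iron lists lose their call (adjusted p = 0.0504 and 0.126).

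Other large falls were those of YNL194C, which was at background with spermidine and at least 22.2-fold lower than in the mean of the controls, PNS1 (log2 -3.73 ± 0.32), TMA10 (log2 -3.53 ± 0.76) and the proline permease gene PUT4 (log2 -3.45 ± 0.47). Without the background limit, YNL194C had log2 -5.06 against controls 1, 4 and 5 and -9.97 against controls 2 and 3, so its bound depends on the controls. Among genes of polyamine metabolism and transport, SPE2, S-adenosylmethionine decarboxylase, fell 1.76-fold (log2 -0.82 ± 0.18, limma adjusted p = 0.00296). The polyamine transporter gene TPO5 rose 2.34-fold and TPO2 fell 2.11-fold. HYP2, which encodes the hypusinated factor eIF5A, had log2 -0.20 ± 0.07 (adjusted p = 0.0387), a call that is lost without the quantile step and without each of 8 single arrays (control 1, control 3, control 4, control 5, spermidine 1, spermidine 3, spermidine 4 and spermidine 5). SPE1 (log2 -0.01 ± 0.18), SPE4 (-0.02 ± 0.19), the antizyme gene OAZ1 (0.35 ± 0.17) and GCN4 (-0.12 ± 0.12) did not pass the threshold. Neither the polyamine metabolism list (1 of 6 lower, adjusted p = 0.670) nor that of polyamine transport (3 of 12 higher, 1 lower, adjusted p = 0.515) passed camera.

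Over all 5102 genes tested, 911 were higher and 751 lower with spermidine (limma, Benjamini-Hochberg adjusted p under 0.05), 32.6% of the genes, of which 291 and 259 by at least 2-fold. Of 47 lists, 9 passed camera upwards and 6 downwards, and with an estimated correlation only the unfolded protein response list did. With single arrays left out, these list medians moved by more than 1.5-fold or lost their call. Ribosome biogenesis lost the call at -0.12 without spermidine 4, and kept it at -0.16 without control 4. Hexose transporters stayed called at -0.54 without spermidine 4. The iron regulon lost the call at -0.29 without control 1, -0.34 without control 2, -0.25 without control 3, -0.30 without control 5, -0.30 without spermidine 1, -0.32 without spermidine 3 and -0.27 without spermidine 5. Of the 176 named genes called, 124 kept their call in every setting in which they were tested and 0 reversed, 138 of the 176 being tested with the dimmest 50% left out.

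**Figure D1:**
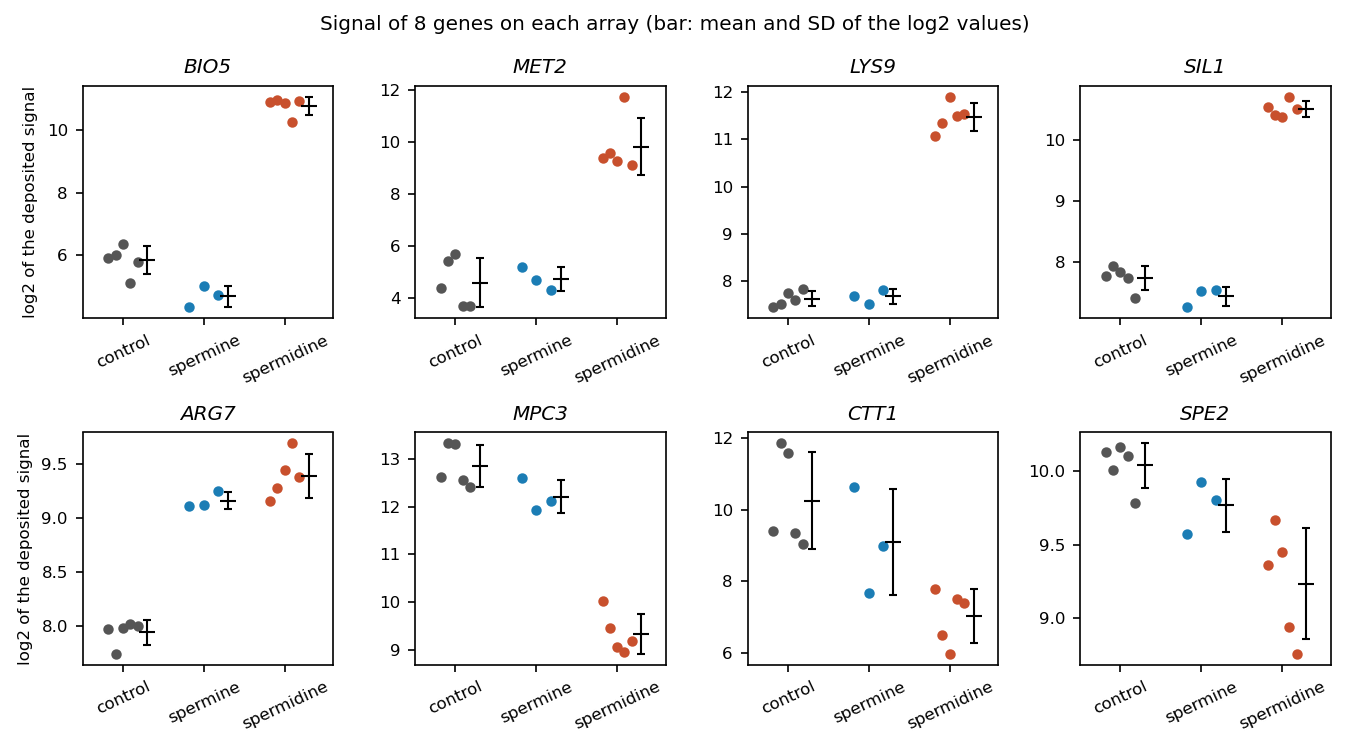
Points show the log2 of the deposited signal of 8 genes on each of the 5 control, 3 spermine and 5 spermidine arrays, with bars for mean and SD. MET2 on the spermidine 4 array stands at a signal of 3480 against 562 to 766 on the other spermidine arrays, and ARG7 is higher with both polyamines.

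Spermine, which carries an aminopropyl group more than spermidine, was compared with the same controls. ARG7, ornithine acetyltransferase of arginine synthesis, had a signal of 247 ± 18.6 (SD, n = 5) in controls and 571 ± 31.3 (SD, n = 3) with spermine, a 2.28-fold rise (log2 1.19 ± 0.14, limma adjusted p = 0.00403). It was the 1 gene of 5102 called higher, and 0 were called lower. At an unadjusted p under 0.05 there were 433 genes, 268 higher and 165 lower, where 255 are expected by chance. Leading genes of the spermidine response were not called with spermine in the main fit. With controls 2 and 3 and spermine 1 set apart as a block, the genes called included STR3 (log2 1.24), MPC3 (log2 -0.57) and INO1 (log2 0.87). That setting was chosen after seeing the data. BNA2, at background in the mean of the controls, had a signal of 45.7 ± 18.7 (SD, n = 3) with spermine. Its controls differed: with spermidine the log2 value was 6.74 against controls 1, 4 and 5 and 4.15 against controls 2 and 3. The level on controls 2 and 3 was therefore higher than on the other controls. In the main fit, values of the other leading genes with spermine were log2 1.21 ± 0.36 for STR3, 0.14 ± 0.57 for MET2, 0.01 ± 0.18 for LYS9 and -0.23 ± 0.17 for BIO4.

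Genes of several amino acid pathways shifted upwards as lists by camera, although of their members only ARG7 was called over all genes. In branched-chain amino acid synthesis 13 of 13 genes had values above control, 0 were called over all genes and 6 were higher adjusted over the list alone (median 0.49, adjusted p = 6.32e-09, adjusted p = 0.0759 with an estimated correlation). Histidine synthesis had 7 of 7 above control, 0 called and 4 adjusted over the list alone (median 0.69, adjusted p = 1.18e-04, adjusted p = 0.0759 with an estimated correlation). HIS3 and HIS5 stood at log2 0.69 and 1.07. In arginine synthesis 8 of 8 were above control, with 1 called and 4 adjusted over the list alone (median 0.55, adjusted p = 9.76e-07, adjusted p = 0.0759 with an estimated correlation). In lysine synthesis 9 of 9 were above control, with 0 called and 3 adjusted over the list alone (median 0.25, adjusted p = 2.66e-04, adjusted p = 0.205 with an estimated correlation). Methionine synthesis had 0 called and 5 adjusted over the list alone (median 0.26, adjusted p = 0.00666, adjusted p = 0.827 with an estimated correlation). NAD synthesis had 0 called and 4 adjusted over the list alone (median 0.36, adjusted p = 9.63e-04, adjusted p = 0.205 with an estimated correlation). The arginine, lysine, methionine and NAD lists are not independent evidence. Aromatic amino acid synthesis (median 0.38, adjusted p = 0.00351, adjusted p = 0.397 with an estimated correlation) and the phosphate regulon (median 0.39, adjusted p = 3.98e-04, adjusted p = 0.238 with an estimated correlation) had 4 members each adjusted over the list alone and 0 over all genes.

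Further upward lists had 0 members called under either adjustment. Cytosolic ribosomal proteins had 68 of 81 above control (median 0.16, adjusted p = 3.67e-05, adjusted p = 0.859 with an estimated correlation). Purine synthesis and one-carbon metabolism had 18 of 19 above control (median 0.36, adjusted p = 0.00179, adjusted p = 0.690 with an estimated correlation). The median of the purine list was 0.52 with controls 1, 4 and 5 and spermine 2 and 3 alone, and 0.02 (adjusted p = 0.625) with controls 2 and 3 and spermine 1 alone. Amino acid permeases had 15 of 19 above control (median 0.18, adjusted p = 0.0343, adjusted p = 0.233 with an estimated correlation). Downward lists had 0 members called over all genes. Biotin synthesis and uptake, not independent evidence, had 5 of 6 below control and 2 lower adjusted over the list alone (median -0.61, adjusted p = 6.12e-04, adjusted p = 0.372 with an estimated correlation), BIO5 at log2 -1.18 ± 0.24. The mean of this list was -0.46, -0.58 and -0.78 on the spermine arrays, -0.84 on control 4 and between 0.04 and 0.31 on the other controls. The BIO5 signals with spermine, 20.2 to 32.2, lay near the background level of 18.1. The unfolded protein response had 2 members lower adjusted over the list alone (median -0.17, adjusted p = 0.0177, adjusted p = 0.433 with an estimated correlation). With the arrays that deviate together as a block, adjusted p = 0.0900 for this list and 0.0516 for mitochondrially encoded genes. Histones also had 2 lower (median -0.53, adjusted p = 0.00179, adjusted p = 0.323 with an estimated correlation). The remaining downward lists had 0 under either adjustment. They were proteasome genes (median -0.14, adjusted p = 7.56e-04, adjusted p = 0.566 with an estimated correlation) and heat shock chaperones (median -0.27, adjusted p = 0.00255, adjusted p = 0.690 with an estimated correlation). General stress genes (median -0.21, adjusted p = 0.0313, adjusted p = 0.860 with an estimated correlation), anaerobic genes (median -0.26, adjusted p = 0.0177, adjusted p = 0.458 with an estimated correlation) and mitochondrially encoded genes (median -0.24, adjusted p = 0.0343, adjusted p = 0.458 with an estimated correlation) were the others. Controls 2 and 3 and spermine 1 had higher stress gene values than the other control and spermine arrays, with 0.48 for the general stress list on spermine 1 and -0.80 and -0.51 on spermine 2 and 3.

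By camera, 11 lists passed upwards and 8 downwards with spermine, 0 with an estimated correlation and 7 by fry, and 8 of the 19 lost their call when a single array was left out. The count of genes depends on the fit, with 34 higher and 12 lower under array weights, and 23 and 11 with the arrays that deviate together as a block, a setting chosen after seeing the data. It depends on single arrays too: without spermine 3 it was 0 higher, ARG7 then having log2 1.14 and no longer passing the threshold, without spermine 2 it was 3, without control 1 it was 4, and without control 4 there was 1 lower gene.

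The medians of several lists with spermine depended on single arrays, and all cases in which a call ended or the median moved by more than 1.5-fold are given here. Lysine synthesis stayed called at 0.17 without spermine 1 and 0.42 without spermine 3. Purine synthesis lost the call at 0.27 without spermine 1, and kept it at 0.23 without control 5. Biotin synthesis stayed called at -0.94 without control 4. Amino acid permeases lost the call at 0.17 without control 3, 0.16 without control 4, 0.17 without control 5 and 0.15 without spermine 1. Heat shock chaperones lost the call at -0.16 without control 2, -0.17 without control 3 and -0.09 without spermine 2, and kept it at -0.46 without control 5 and -0.77 without spermine 1. General stress genes lost the call at 0.03 without control 2, 0.00 without control 3, 0.01 without spermine 2 and -0.11 without spermine 3, and kept it at -0.34 without control 1, -0.35 without control 4, -0.36 without control 5 and -0.47 without spermine 1. Mitochondrially encoded genes lost the call at -0.42 without control 2, -0.17 without control 3, -0.14 without spermine 2 and -0.08 without spermine 3, and kept it at -0.57 without control 1 and -0.91 without spermine 1. The phosphate regulon stayed called at 0.21 without spermine 2. Anaerobic genes lost the call at -0.20 without control 1 and -0.27 without spermine 2. The unfolded protein response lost the call at -0.14 without control 3 and -0.14 without control 4, and kept it at -0.09 without spermine 3. Histones stayed called at -0.27 without spermine 2. Proteasome genes lost the call at -0.08 without spermine 2, and kept it at -0.08 without spermine 1 and -0.23 without spermine 3. With controls 2 and 3 and spermine 1 alone, where the lone spermine array is assumed to vary like the other groups, 10 of the 19 lists kept their call. Methionine synthesis then had a median of 0.10 (adjusted p = 0.280), against 0.39 with the other control and spermine arrays, general stress genes -0.59 (adjusted p = 1.32e-07) against 0.05, and ribosome biogenesis 0.43 (adjusted p = 4.39e-08) against -0.08 (adjusted p = 0.0196). These arrays were set apart after seeing the same values, so these p-values are too small.

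**Figure D2:**
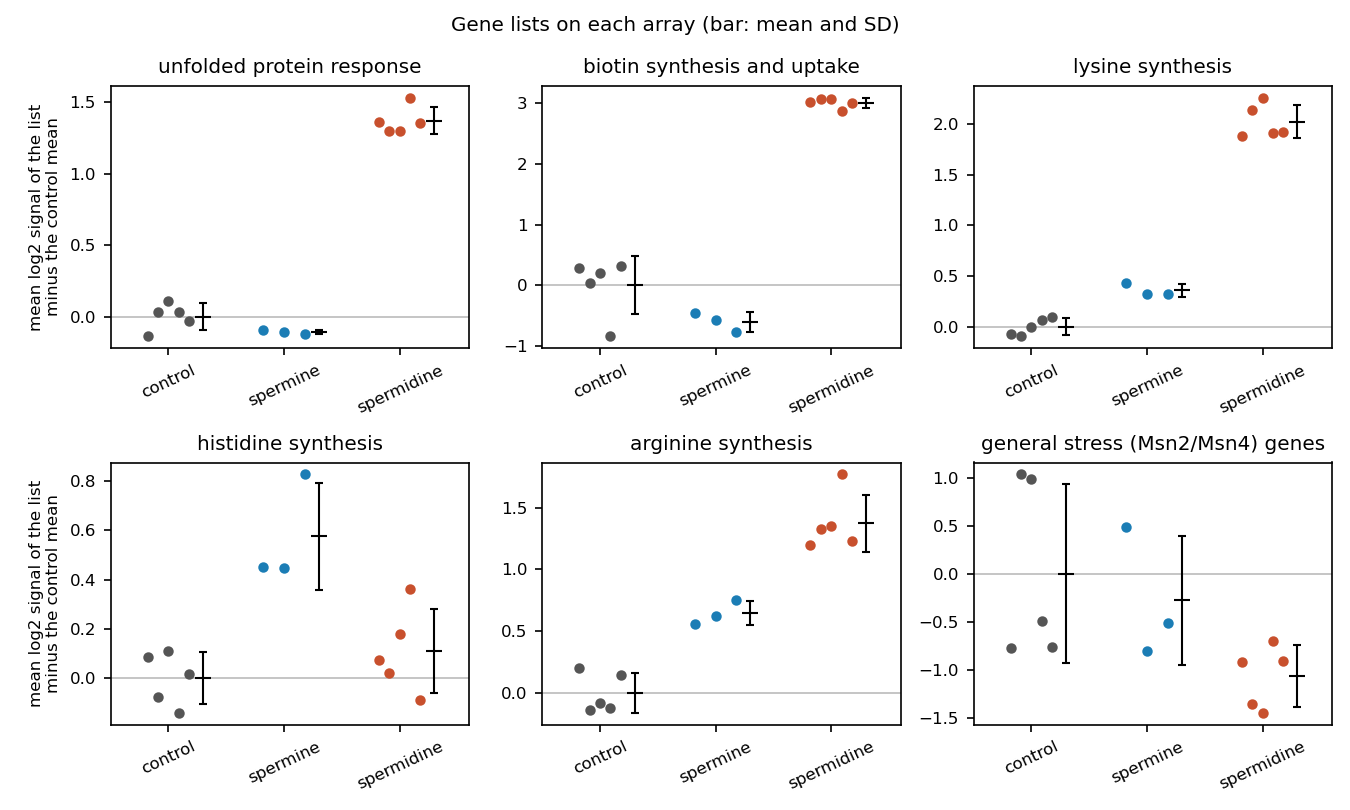
Points show the mean log2 signal over the members of 6 gene lists on each array, minus the mean of the 5 controls, with bars for mean and SD. The unfolded protein response list lies between 1.30 and 1.53 on the spermidine arrays, and the general stress list spans -0.77 to 1.03 among the controls.

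The polyamines were then set against each other, spermine minus spermidine, with doses and times not given, so that the values are side by side without matched doses. BIO5 was 67.5-fold lower with spermine (log2 -6.08 ± 0.24, 95% interval -6.58 to -5.57, limma adjusted p = 9.35e-10), MET2 36.1-fold (log2 -5.17 ± 0.57), BIO3 26.1-fold, BNA2 18.2-fold, STR3 16.5-fold and LYS9 14.1-fold. Signals with spermine were 20.2 to 32.2 for BIO5 and 19.6 to 36.7 for MET2, near the background level of 18.1. The size of the folds of BIO5 and MET2 is therefore uncertain. PNS1 was 9.80-fold higher with spermine (log2 3.29 ± 0.37), MPC3 7.37-fold, the ceramidase gene YPC1 6.93-fold, the uracil permease gene FUR4 6.39-fold and YRO2 12.2-fold. GCV1 of the glycine cleavage system was 6.79-fold higher and ARO10, a decarboxylase of amino acid breakdown, 6.66-fold. Of the polyamine transporters, TPO2 was higher with spermine (log2 1.55 ± 0.28, interval 0.94 to 2.16), and TPO5 (log2 -0.92 ± 0.16, interval -1.26 to -0.58) and TPO4 (log2 -0.95 ± 0.29, interval -1.58 to -0.32) were lower. The call of TPO4 ended without spermine 2, spermine 3, spermidine 2, spermidine 3, spermidine 4 and spermidine 5 in turn (log2 -0.98 to -0.69).

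In the unfolded protein response list 19 of 21 genes were lower with spermine than with spermidine and 1 was higher, 19 and 1 adjusted over the list alone (median log2 -1.38, camera adjusted p = 3.47e-16, adjusted p = 0.0154 with an estimated correlation). SIL1 was 8.42-fold and EUG1 9.79-fold lower, and HAC1 was higher by log2 1.15. In methionine synthesis 18 of 26 genes were lower, and 19 lower and 3 higher adjusted over the list alone (median log2 -1.69, camera adjusted p = 3.60e-08, adjusted p = 0.433 with an estimated correlation). Biotin genes were lower in 5 of 6 cases, 6 adjusted over the list alone (median log2 -3.85, camera adjusted p = 4.79e-09, adjusted p = 0.0759 with an estimated correlation). For lysine 7 of 9 were lower, 7 adjusted over the list alone (median log2 -1.65, camera adjusted p = 7.05e-09, adjusted p = 0.0542 with an estimated correlation). Arginine synthesis had 5 of 8 lower, 5 adjusted over the list alone (median log2 -0.91, camera adjusted p = 0.0109, adjusted p = 0.417 with an estimated correlation). NAD synthesis had 5 of 14 lower and 1 higher, 7 and 2 adjusted over the list alone (median log2 -0.49, camera adjusted p = 0.0343, adjusted p = 0.436 with an estimated correlation). These 5 lists are not independent evidence. The phosphate regulon had 6 of 12 lower, 6 adjusted over the list alone (median log2 -0.52, camera adjusted p = 0.0313, adjusted p = 0.489 with an estimated correlation). Of the S-adenosylmethionine cycle 6 of 18 were lower and 1 higher, 7 and 2 adjusted over the list alone (median log2 -0.31, camera adjusted p = 0.0493, adjusted p = 0.625 with an estimated correlation). The higher members were NMA1 of the NAD list (log2 0.92) and ARO9 of the S-adenosylmethionine list (log2 2.31).

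Purine synthesis and one-carbon metabolism had 9 of 19 genes higher with spermine than with spermidine, and 12 higher and 1 lower adjusted over the list alone (median log2 0.87, camera adjusted p = 7.56e-04, adjusted p = 0.672 with an estimated correlation). GCV2 was 4.62-fold and MTD1 3.39-fold higher, the call of GCV2 ending without spermine 1 and spermine 3 (log2 1.71 to 2.02). In the respiratory chain 13 of 35 were higher, 13 adjusted over the list alone (median log2 0.37, camera adjusted p = 1.16e-04, adjusted p = 0.607 with an estimated correlation), with CYC7 6.12-fold. Hexose transporters were higher in 5 of 9 cases, 8 adjusted over the list alone (median log2 0.83, camera adjusted p = 0.00591, adjusted p = 0.397 with an estimated correlation). General stress genes had 7 of 46 higher and 1 lower, 7 and 1 adjusted over the list alone (median log2 0.73, camera adjusted p = 0.00154, adjusted p = 0.860 with an estimated correlation). This call rests on spermine 1, without which adjusted p = 0.103. For the iron regulon 9 of 26 were higher and 2 lower, 10 and 2 adjusted over the list alone (median log2 0.43, camera adjusted p = 0.0493, adjusted p = 0.768 with an estimated correlation). Ribosome biogenesis had 6 of 86 higher, 3 adjusted over the list alone (median log2 0.30, camera adjusted p = 1.18e-04, adjusted p = 0.860 with an estimated correlation). Of cytosolic ribosomal proteins 5 of 81 were higher, 0 adjusted over the list alone (median log2 0.13, camera adjusted p = 0.00475, adjusted p = 0.860 with an estimated correlation). Among translation factors 4 of 36 were higher and 1 lower, 1 higher adjusted over the list alone (median log2 0.18, camera adjusted p = 0.0493, adjusted p = 0.860 with an estimated correlation). Of all genes 481 of 5102 were higher, a larger share than in ribosome biogenesis and ribosomal proteins and near that of translation factors. Lower members were AMS1 of the stress list (log2 -3.03), FTH1 and AFT2 of the iron list (log2 -0.76 and -0.59) and HEF3 of the translation list (log2 -0.53). The call of HEF3 ended in 12 of the 13 fits without a single array.

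Some genes and lists did not pass the threshold between the polyamines, which does not show that they were alike. ARG7 was -0.25 ± 0.14 (interval -0.56 to 0.06, adjusted p = 0.248) on the log2 scale, SPE1 0.18 (interval -0.27 to 0.62), SPE2 0.55 (interval 0.10 to 0.99, adjusted p = 0.0751), OAZ1 -0.35 (interval -0.76 to 0.06), HYP2 0.10 (interval -0.08 to 0.27) and GCN4 0.12 (interval -0.18 to 0.41). In histidine synthesis 3 of 7 genes were higher with spermine, 3 adjusted over the list alone. As a list it had a median of 0.51 (camera adjusted p = 0.0598, fry adjusted p = 0.00935). Branched-chain amino acid synthesis had a median of -0.12 (camera adjusted p = 0.843).

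Over all genes 481 were higher and 569 lower with spermine than with spermidine, 203 and 235 by at least 2-fold. Of these 1050 genes, 892 had also changed between spermidine and control. Both contrasts use the same spermidine arrays with opposite sign, so the directions of these genes are not independent between them. The higher count was 298 without spermine 2 and 304 without spermine 3. With single arrays left out, these list medians moved by more than 1.5-fold or lost their call. The S-adenosylmethionine cycle lost the call at -0.31 without control 3, -0.31 without control 5, -0.18 without spermine 1, -0.29 without spermidine 2, -0.28 without spermidine 3 and -0.30 without spermidine 4. NAD synthesis lost the call at -0.39 without spermine 2 and -0.48 without spermine 3. Ribosomal proteins lost the call at 0.04 without spermidine 4, and kept it at 0.23 without spermine 1. Translation factors lost the call at 0.18 without control 2, 0.18 without control 3, 0.18 without control 4, 0.18 without control 5, 0.19 without spermine 2, 0.21 without spermine 3, 0.17 without spermidine 1, 0.12 without spermidine 4 and 0.16 without spermidine 5. General stress genes lost the call at 0.33 without spermine 1. The iron regulon lost the call at 0.43 without control 2, 0.43 without control 3, 0.43 without control 5, 0.33 without spermine 1, 0.41 without spermine 3, 0.40 without spermidine 1, 0.44 without spermidine 3, 0.42 without spermidine 4 and 0.41 without spermidine 5. The phosphate regulon lost the call at -0.40 without spermine 1 and -0.38 without spermine 3.

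Both contrasts share the controls, which by itself correlates their fold changes. Over genes, which are not independent replicates, the fold changes of spermidine and spermine correlated at r = 0.386. In 100 simulated data sets with no effect of either polyamine the mean r was 0.433. These r values cannot be set against each other, because the real spermidine changes spread widely (variance 0.540) and the simulated ones held only noise. The covariance, which is not divided by that spread, was 0.0835 against a mean of 0.0241 in the simulation. Simulated genes and arrays vary independently, while real ones deviate together. The difference between these covariances therefore does not by itself show a shared response. With separate controls for each polyamine, over 20 splits, r had a median of 0.249 and ranged from -0.0049 to 0.352, and the covariance had a median of 0.0614. ARG7 was the 1 gene called in the same direction with both, where independent lists give 0.179 higher and 0 lower.

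**Figure D3:**
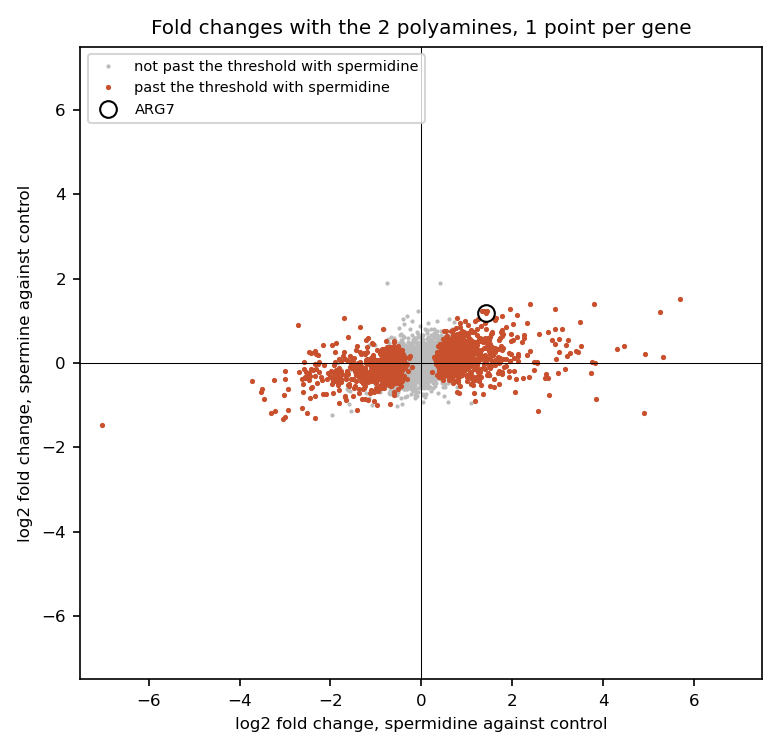
Each of the 5102 points is a gene, with its log2 fold change with spermidine on the horizontal and with spermine on the vertical axis, and genes past the threshold with spermidine in colour. The cloud is wide along the spermidine axis and narrow along the spermine axis, and ARG7 is ringed at 1.43 and 1.19.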

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

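All tests weighed here were chosen after the result was seen except the splits for spermidine against control and spermine against spermidine. A sample far from the others of its group was found in 16 of 148 groups of values, where chance gives about 7.4.

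Spermidine 4 stood apart in several genes and lists. It was high in MET2, at a signal of 3480 (others 562 to 766), and MET10, at 2834 (530 to 743). In BIO5 it was low, at 1218 (1855 to 1969). The list means of spermidine 4, in log2 units relative to the control mean, were 3.18 for methionine synthesis (others 1.74 to 1.86), 0.93 for the S-adenosylmethionine cycle (0.49 to 0.60) and 1.77 for arginine synthesis (1.20 to 1.35). They were 1.53 for the unfolded protein response (1.30 to 1.36), -1.35 for hexose transporters (-0.74 to -0.62) and -0.36 for cytosolic ribosomal proteins (0.06 to 0.16). Control 4 was low in BIO3 (84.4, others 238 to 282), ANB1 (129, others 282 to 336), the biotin list (-0.84, others 0.04 to 0.31), the iron regulon (-0.35, others 0.05 to 0.15) and anaerobic genes (-0.34, others 0.03 to 0.16). Control 3 was high in TPO5 (308, others 217 to 231). Control 2 had a signal of 1025 on a 25S ribosomal RNA probe set, against 8327 to 11108 on the other controls. Outside the genes tested, 94 unnamed probe sets were higher and 160 lower with spermidine, and of probe sets of several genes 43 were higher and 32 lower.

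Controls 2 and 3 and spermine 1 deviated from their group means together: across groups, correlations within this set and within the other arrays were -0.06 to 0.58, and between the sets -0.57 to -0.23. The sets were drawn from the same values. Deviations from a group mean sum to 0, so the negative values between the sets follow in part from the others. RNA degradation or labelling stays open, as the readings differ. Of the other 5 control and spermine arrays, 4 had a lower ACT1 3'/5' ratio than each of the 3, and control 1 alone a higher one. The same ratio for the TBP gene did not set the 3 apart. It was 3.55 and 2.92 on controls 2 and 3 and 2.90 on spermine 1. On controls 1, 4 and 5 it was 4.33, 2.65 and 2.93, and on spermine 2 and 3 it was 3.67 and 3.57. Of the 3 arrays, control 2 alone had low signals on ribosomal RNA probe sets. The quantile step is argued against, since the lower correlation of spermine 1 with controls 2 and 3 was 0.495 in the values as deposited. A culture or hybridisation batch stays open, as the labels give none, and no biological explanation was tested.

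If the arrays are independent samples, chance is argued against for spermidine against control. There 1 of 100 splits drawn from the 126, the real one, gave 1662 genes and the highest other 30. The same holds for spermine against spermidine, where 1 of 56 splits, the real one, gave 1050. The highest other, 125, set spermidine 1, 4 and 5 apart from spermidine 2 and 3 and the spermine arrays. Such splits cannot tell the treatment from a culture or batch shared within a group, and the labels give none. Chance cannot be excluded for spermine against control: 5 of 56 splits, the real one among them, gave at least the real count of 1 gene. The highest, 627 genes, was the split of controls 2 and 3 and spermine 1 from the rest, which points to a structure of the samples larger than the spermine effect.

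Small RNA genes were lower with spermidine, 116 of 136 tRNA, snoRNA and snRNA genes. Probe sets shared between tRNA copies are argued against as the whole cause, since a share of 0.848 of the 46 snoRNA and snRNA genes with their own probe set fell, and so is the quantile step, since a share of 0.838 of all small RNA genes fell in the values as deposited. How much small RNA was recovered or labelled on each array cannot be told apart from the treatment. The range of the small RNA median over the 5 controls was 0.323 of the difference between the groups. A 25S ribosomal RNA probe set was also lower with spermidine, at 2189 to 8148. It read 8327 to 11108 on the controls other than control 2, at 1025, and 8828 to 10123 with spermine. An 18S ribosomal RNA probe set overlapped, at 10461 to 14472 with spermidine and 2058 to 17807 in controls. A biological effect of spermidine on these genes stays open and was not tested.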

How the results depend on the processing

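The direction of every named gene that was called held in all settings. With spermidine, 124 of 176 called named genes kept their call in every setting in which they were tested, and between the polyamines 70 of 159. With the dimmest 50% left out only 138 and 125 of these were tested. By camera with the preset correlation, 9 of 15, 8 of 16 and, for spermine, 7 of 19 lists kept their call. Camera with an estimated correlation left 1 list for spermidine, 0 for spermine and 1 for the direct contrast, and fry gave 7 for spermine. With the dimmest 50% left out the direct contrast had 10 lists. Array weights gave 34 genes higher and 12 lower with spermine, and 33 changed by both polyamines, and the general stress list with spermine turned to 0.0469 (adjusted p = 0.789). Arrays of the same replicate number did not deviate alike between groups (r of -0.57 to 0.20). This cannot exclude a batch of replicates whose effect differs by group. The highest other split for spermidine against control, 30 genes, put controls 1, 4 and 5 with spermidine 2 and 3. For spermine against spermidine, 125 genes, it set spermidine 1, 4 and 5 apart. Spermine 1, not spermine 2 and 3, deviated with controls 2 and 3. With a replicate block spermine had 1 lower gene and the direct contrast 264 higher and 358 lower. Leaving out 1 array at a time, genes higher with spermine ranged from 0 to 4, lower from 0 to 1, changed by both from 0 to 4, and the direct contrast had 298 to 491 higher. With the controls split between the polyamines, the correlation had a median of 0.249 and a lowest value of -0.0049, and 0 genes (median and lowest) to 30 (highest) changed with both. The next fits, up to that without small RNA genes, were chosen after seeing the data. With controls 2 and 3 and spermine 1 as the only control and spermine arrays, spermine had 0 higher and 1 lower gene, and the direct contrast 220 and 317. The lone spermine array is assumed there to vary like the other groups. With that array set as a block, spermine had 23 higher and 11 lower genes, and 0 lists with an estimated correlation; the sets come from the same expression values, so these p-values are too small. With the other controls and spermine arrays alone, the ribosome biogenesis list turned to -0.0848 (adjusted p = 0.0196) with spermine and the general stress list to 0.0545 (adjusted p = 0.987), where controls 2 and 3 and spermine 1 alone gave 0.43 and -0.59. Without small RNA genes, 632 genes were lower with spermidine. The causes of these differences were not tested. The filter by Schizosaccharomyces pombe probe sets was not run, since the array carries none.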

Other observations

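All tests in this part were chosen after the result was seen. Small RNA genes, not among the fixed lists, formed 15.4% of the genes lower with spermidine. Of 88 tRNA genes 75 fell (median log2 -1.27), of 44 snoRNA genes 37 (median -1.51) and of 4 snRNA genes 4 (median -1.36), and none rose. Only 2 of the 88 tRNA genes have their own probe set, so the tRNA counts rest on probe sets shared between copies, against 43 of the 44 snoRNA genes with their own. SNR37 fell 6.10-fold and SNR3 6.02-fold. With spermine 0 of them were called by limma, where 85 of 88 tRNA genes had values below control, and 42 tRNA, 33 snoRNA and 4 snRNA genes were higher with spermine than with spermidine. The median of small RNA genes on each array, relative to the control mean, was -2.14 to -0.93 with spermidine, -0.27 to 0.19 in controls, -0.72 on spermine 1, and 0.07 and 0.09 on spermine 2 and 3 (exact permutation test of spermidine against control, two-sided, p = 0.00794, n = 5 and 5, the smallest p this design allows).

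Several genes of one-carbon metabolism had values of opposite sign with the polyamines. GCV1 had log2 -1.70 with spermidine and 1.06 with spermine, GCV2 -1.36 and 0.85, and MTD1 -1.23 and 0.54, the spermine values not being called. Against controls 1, 4 and 5 the spermidine values of GCV1 and GCV2 were -0.79 and -0.59 and not called, and against controls 2 and 3 they were -3.06 and -2.50.

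A hypothesis was that spermine gives the spermidine response at a smaller size. Of the lists past the threshold with both polyamines, 8 moved the same way and 2, biotin synthesis and the unfolded protein response, the opposite way. With an estimated correlation 0 of the 19 spermine lists kept their call, whichever way they moved, so that test cannot decide. The spermine call ended without each of 4 single arrays for general stress genes, 3 for heat shock chaperones and 2 for the unfolded protein response. With the array set as a block the call of the unfolded protein response list also ended (adjusted p = 0.0900), while biotin synthesis kept its call there (-0.57, adjusted p = 0.00901), within each set of arrays and without each of 13 single arrays. Control 4, however, lay below all spermine arrays in the biotin list (-0.84 against -0.78 to -0.46), so the lists do not settle it. The requirement that such lists also pass with an estimated correlation was added after their result was known. By the first wording, which asked for 2 lists with the preset correlation alone, the hypothesis would have been argued against. Genes at least 2-fold higher with spermidine on part of the controls had a median log2 of 0.12 with spermine (0.03 to 0.18 over the splits of the controls) and 1.36 with spermidine on the remaining controls. Genes at least 2-fold lower had -0.18 (-0.25 to 0.12) and -1.46, so their sign turned with spermine in some splits. Only the controls were held out. The same spermidine arrays picked the genes and gave the 1.36 and -1.46, so the choice enlarges the spermidine values and not the spermine values. The median of all genes with spermine was 0.02. With the array set as a block, 26 of the 34 genes called with spermine were called with spermidine in the same direction and 0 in the opposite one. Both use the same controls, which favours the same sign, and the sets were chosen after seeing the values. Whether a part of the response is shared stays open, with doses and times not given and chance not excluded for spermine.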
